A study of Danio rerio with 24 samples.

How the data were processed

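RNA was measured in GFP+ and GFP- cells sorted from Tg(sqET20) zebrafish larvae at 5 days post fertilization, 1, 3 and 5 h after treatment with 300 uM neomycin and 1 h after mock treatment, in 3 replicates per group and 24 libraries in all. Per the labels, the libraries were made from polyadenylated RNA with a TruSeq kit, and the authors named CASAVA 1.8.2, TopHat 1.4.1 and Cufflinks 1.3 and the genome build danRer7. The authors deposited FPKM (fragments scaled to transcript length and to mapped fragments), one column per library and one row per Ensembl gene. The annotation release, the strand setting and any filter by the authors are not given in the sources used here, and neither are gene positions. Total counts per library are not known. Relative depth was read from genes under 0.15 FPKM, as the most frequent ratio between 2 libraries (within 0.02 log2). A few abundant transcripts can shift all other values of a library.

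The table held 31199 rows, and the first row of each of 31087 Ensembl IDs was used (112 repeats were dropped). A table of gene names gave a symbol to 20499 IDs and none to 10588. For many zebrafish genes it gives the symbol of the mammalian ortholog in capitals, so paralogs can share a symbol; the ID with the highest mean FPKM then stands for the symbol. Genes with FPKM of 1 or more in at least 3 of the 24 libraries were tested (21866). Values were taken as log2(FPKM + 1) with no further scaling. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all libraries, with variances moderated along an intensity trend. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. The contrasts were each neomycin time against mock within GFP+ and within GFP- cells, the difference of these changes between the populations at each time, GFP+ against GFP- cells of mock larvae, and 5 h against 3 h in GFP+ cells. Replicate numbers were not used as a block because the labels do not say that they pair samples. Libraries of 3 h and 5 h carry another date than mock, and no model can separate that date from the treatment within a population. Mock libraries are of 1 h only, so the same holds for the later time of sampling.

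The contrasts, the test, the first set of other settings and 25 gene lists with 1090 members were fixed before the data were examined, and 861 members were matched to an ID. The lists cover hair cells, lateral line and supporting cells, Notch, Fgf, Wnt/beta-catenin, Jak/Stat3, immediate early and AP-1 genes, heat shock and unfolded protein, S phase and mitosis, G1 cyclins and cell cycle inhibitors, p53 and apoptosis, NF-kB and inflammation, Bmp and Tgf-beta, chemokine and migration, retinoic acid and steroid, ribosome biogenesis, and glycolysis and hypoxia. They also cover markers of other cell types: skeletal muscle, neuron, retina and lens, blood, epidermis, pigment cell and neural crest glia, gut, liver, pancreas and kidney, and vessel, cartilage and fibroblast. Each list with at least 5 tested members was tested with camera (limma) at a preset correlation of 0.01, adjusted over 275 tests of lists and contrasts. Camera called 103 of these, and 0 of the 103 held with a correlation estimated from the data; fry, which tests a list by itself, called 46 of the 103 and 9 others. Counts of members adjusted over all genes are followed by those adjusted over the list alone, and where fry ended a camera call its adjusted p is given ("by fry").

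The genes named in the text follow a fixed rule. For the 3 GFP+ times and the GFP+ to GFP- comparison it takes the 6 largest rises and falls among called genes whose groups do not overlap, with a mean of 5 FPKM or more in the higher group and a gene symbol that is not clone-like. For other contrasts it takes the 3 largest, for described lists up to 4 members with the smallest p, and a set of genes is reported whatever the result. Symbols with certain first letters, FO among them, counted as clone-like under the rule's wording. This leaves the fos family and other genes out of the largest changes but not out of the lists. The 10 (or 3) largest outside small-RNA loci were added after the data were seen. Of the fixed set, axin2 and ccnd1 had no match and are not analysed here. Some genes that the rule takes are not reported here. Named genes with an absolute log2 change under 1 do not pass a threshold that also asks for a log2 change of 1.

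Other settings fixed in advance were a pseudocount of 0.1, no filter and a stricter filter (5 FPKM), median-of-ratios and quantile scaling, zeros set to missing, a model of the contrast's own groups, a threshold of 1 on the log2 change, a replicate block by number or by sort, and each library left out in turn. Settings chosen after seeing the data were the subtraction of an estimated GFP- share from each GFP+ library, leaving out the 4 GFP+ libraries numbered 1, which have the highest share in the 1, 3 and 5 h neomycin groups, and scaling to the FPKM sum outside the 10 most abundant loci. The share was the median ratio to the GFP- group over 43 blood, neuron and retina markers (18, 12 and 13) with at least 20 FPKM in GFP- cells. The blood markers alone gave 0.816% to 4.75%, less than the share subtracted in each of the 12 libraries, so the subtraction takes blood genes toward 0 by construction, and its outcome for single markers of these 3 lists is not reported. The pipeline was tested on simulated data for the 1 h contrast with 19179 genes: it called 29 of 66 genes with a true log2 change of 0.5, 51 of 67 at 1 and 67 of 67 at 2, with 9 false calls. Figures were drawn with matplotlib.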

Results

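Gene expression was measured by RNA sequencing in cells sorted from zebrafish larvae of the Tg(sqET20) line, whose GFP marks cells of the lateral line among others. The lateral line is a set of superficial sensory organs (neuromasts) in which hair cells are surrounded by supporting cells, and the antibiotic neomycin kills the hair cells. Larvae at 5 days post fertilization were treated with 300 uM neomycin or mock treated. They were then dissociated, and living GFP+ and GFP- cells were sorted. The 24 libraries form 8 groups of 3, GFP+ and GFP- cells 1, 3 and 5 h after neomycin and 1 h after mock treatment. Mock and 1 h libraries carry the date Mar2012, and 3 h and 5 h libraries carry Apr2012.

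The values are not read counts, so no counting interval is given. The low values give each library's depth relative to the median library, which ran from 0.729 to 1.26 over the 24 libraries. In GFP+ cells it was 0.868 to 1.22 in mock, 0.817 to 1.16 at 1 h, 0.729 to 0.84 at 3 h and 0.946 to 1.11 at 5 h. The FPKM sums per library ran from 1147743 to 1602087, and the 10 most abundant loci held 35.8% to 44.4% of each sum. GFP+ libraries had 16625 to 17811 genes at 1 FPKM or more, and GFP- libraries had 19031 to 19607. The first principal component took 65.6% of the variance and put all 12 GFP+ libraries at positive and all 12 GFP- libraries at negative scores.

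The GFP+ and GFP- cells of mock larvae were compared to see what the sort enriched. TSPAN1 (ENSDARG00000052027), a tetraspanin, stood at 171 ± 14.9 FPKM (mean ± SD, n = 3) in GFP+ cells and 0.367 ± 0.121 in GFP- cells. Its log2 fold change ± standard error was 6.98 ± 0.23, and all bracketed values below are given this way, with 3 libraries per group. A dagger (†) marks a call that a model of the contrast's own groups alone (own-groups model) did not make. Other markers of the lateral line were krt15 (ENSDARG00000036840, 6.15 ± 0.24), sox21a (ENSDARG00000031664, 4.84 ± 0.23) and EYA4 (ENSDARG00000012397, 3.99 ± 0.19). The largest differences toward GFP+ cells were in a family of fibronectin type III domain genes. These were fndc7rs3 (ENSDARG00000093150, 8.55 ± 0.29), fndc7rs4 (ENSDARG00000092813, 8.33 ± 0.24), fndc7rs1 (ENSDARG00000092469, 8.15 ± 0.27), FNDC7 (ENSDARG00000077096, 7.81 ± 0.21), fndc7rs2 (ENSDARG00000092552, 7.72 ± 0.23) and fndc7b (ENSDARG00000075676, 7.43 ± 0.22). Next to them came negaly6 (ENSDARG00000089123, 8.05 ± 0.21), cbln20 (ENSDARG00000087476, 7.73 ± 0.20) and cbln18 (ENSDARG00000090969, 7.61 ± 0.20). In the lateral line and supporting cell list 28 of 37 were higher, 7 were lower and 2 did not pass (the same over the list alone, camera adjusted p = 4.48e-10, 0.299 with an estimated correlation). Its median was 2.18, against 2.81 for the epidermis list and 2.06 for the vessel, cartilage and fibroblast list below. In the hair cell list 20 of 36 were higher, 8 were lower and 8 did not pass (20 and 8 adjusted over the list alone, camera adjusted p = 3.44e-06, adjusted p = 0.581 with an estimated correlation). Higher hair cell genes were LHFPL5 (ENSDARG00000045023, 3.15 ± 0.17), a part of the mechanotransduction machinery, pvalb9 (ENSDARG00000071601, 4.36 ± 0.25), a calcium-binding parvalbumin, and s100t (ENSDARG00000055589, 5.80 ± 0.34).

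Markers of other cell types went both ways in this comparison. Of the epidermis list 30 of 37 were higher and 7 lower (the same over the list alone, camera adjusted p = 4.67e-10, 0.486 with an estimated correlation). Examples were ANXA1 (ENSDARG00000026726, 4.43 ± 0.20), col17a1b (ENSDARG00000079011, 5.28 ± 0.25) and the keratin krt5 (ENSDARG00000058371, 5.19 ± 0.27). Of the vessel, cartilage and fibroblast list 23 of 39 were higher, 14 were lower and 2 did not pass (the same over the list alone, camera adjusted p = 0.000119, 0.724 with an estimated correlation). Blood markers were lower in GFP+ cells, 28 of 28 (the same over the list alone, camera adjusted p = 5.57e-10, 0.486 with an estimated correlation). The lysozyme gene lyz (ENSDARG00000057789, -7.51 ± 0.58) and the neutrophil protease npsn (ENSDARG00000010423, -7.00 ± 0.42) were the lowest outside small-RNA loci. They were followed by the embryonic globins hbae3 (ENSDARG00000079305, -6.37 ± 0.36), hbae1.1 (ENSDARG00000089475, -6.34 ± 0.41), HBE1 (ENSDARG00000045143, -6.29 ± 0.33), hbae1.2 (ENSDARG00000088330, -6.19 ± 0.45) and hbae1.3 (ENSDARG00000089124, -6.00 ± 0.43). Similar differences were found for SLC4A1 (ENSDARG00000012881, -6.34 ± 0.29), the red cell anion exchanger, the peroxidase gene EPX (ENSDARG00000019521, -6.32 ± 0.44) and the somatostatin gene sst1.2 (ENSDARG00000033161, -6.10 ± 0.93). Of the neuron list 21 of 22 were lower and 1 did not pass (the same over the list alone, camera adjusted p = 5.35e-08, 0.581 with an estimated correlation). Examples were NEUROD1 (ENSDARG00000019566, -4.79 ± 0.23) and SNAP25 (ENSDARG00000058117, -4.89 ± 0.21). Of the retina and lens list 1 of 23 was higher and 22 were lower (the same over the list alone, camera adjusted p = 2.39e-06, 0.677 with an estimated correlation). An example is the photoreceptor factor crx (ENSDARG00000011989, -4.62 ± 0.20). Each GFP+ library held a share that could be built from the GFP- profile, estimated from 43 blood, neuron and retina markers. It was 2.76% to 3.53% in mock, 1.94% to 3.88% at 1 h, 3.69% to 6.33% at 3 h and 2.56% to 5.6% at 5 h.

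S phase and mitosis genes were lower in GFP+ cells of mock larvae, 54 of 54 (the same over the list alone, camera adjusted p = 5.57e-10, 0.703 with an estimated correlation). Examples were the DNA polymerase subunit POLA1 (ENSDARG00000045308, -1.58 ± 0.097) and the cyclin CCNA2 (ENSDARG00000011094, -2.70 ± 0.19). Fgf pathway genes were mostly higher, and 15 of 25 were higher, 4 were lower and 6 did not pass (15 and 4 adjusted over the list alone, camera adjusted p = 0.000296, adjusted p = 0.703 with an estimated correlation). They included ETV4 (ENSDARG00000018303, 2.73 ± 0.18), a transcription factor downstream of Fgf receptors, FGF10 (ENSDARG00000030932, 2.59 ± 0.18) and FGFR1 (ENSDARG00000011027, 2.18 ± 0.18), against SPRED3 (ENSDARG00000040358, -2.85 ± 0.18). Of the Wnt/beta-catenin list 26 of 43 were higher, 12 were lower and 5 did not pass (27 and 12 adjusted over the list alone, camera adjusted p = 0.000163, adjusted p = 0.724 with an estimated correlation). Examples were the receptor FZD7 (ENSDARG00000027589, 2.69 ± 0.13) and the ligand wnt2 (ENSDARG00000041117, 4.19 ± 0.24). Of the chemokine and migration list 21 of 29 were higher, 4 were lower and 4 did not pass (22 and 4 adjusted over the list alone, camera adjusted p = 5.74e-07, adjusted p = 0.486 with an estimated correlation). Of the Bmp and Tgf-beta list 23 of 40 were higher, 11 were lower and 6 did not pass (24 and 11 adjusted over the list alone, camera adjusted p = 6.3e-05, adjusted p = 0.703 with an estimated correlation). Small-RNA loci could not be checked against host genes. Several were listed at 0 in all 3 mock GFP+ libraries. They include the erythroid microRNA locus MIR451A (ENSDARG00000082898), at 3836, 5038 and 2890 FPKM in the GFP- libraries, MIR142 (ENSDARG00000082167), mir726 (ENSDARG00000082495), SNORD54 (ENSDARG00000083158) and MIR181B1 (ENSDARG00000083588). The limma test called 15235 of 21866 genes at an adjusted p under 0.05, 4736 higher and 10499 lower, a higher share of 31.1%. Median-of-ratios scaling gave 46.9% higher among 14344 calls, and the median log2 difference of all genes moved from -0.36 to -0.042.

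GFP+ cells 1 h after neomycin were compared with mock to find their early response, and both groups share a date. ODC1 (ENSDARG00000007377), which makes polyamines, stood at 386 ± 128 FPKM against 10.7 ± 3.55 in mock (5.04 ± 0.42, adjusted p = 5.91e-08). ATF3 (ENSDARG00000007823), a stress-induced transcription factor, stood at 85.1 ± 47.9 against 2.37 ± 1.84 (4.67 ± 0.50, adjusted p = 1.02e-06). Large rises were also found for the clock gene PER2 (ENSDARG00000034503, 4.34 ± 0.69), the matrix metalloproteinase mmp13a (ENSDARG00000012395, 4.12 ± 0.66) and the MAP kinase phosphatase DUSP5 (ENSDARG00000019307, 4.12 ± 0.40). They were followed by the arginase ARG2 (ENSDARG00000039269, 3.95 ± 0.30), irg1l (ENSDARG00000062788, 3.81 ± 0.36), the RNA-binding protein LIN28A (ENSDARG00000016999, 3.80 ± 0.30) and the complement gene c7b (ENSDARG00000057121, 3.76 ± 0.55). The largest falls were in ARHGEF19 (ENSDARG00000078853, -2.21 ± 0.21), ca15c (ENSDARG00000002259, -2.17 ± 0.54†), tspan2b (ENSDARG00000059202, -2.13 ± 0.51), lad1 (ENSDARG00000022698, -2.12 ± 0.25) and gsdmea (ENSDARG00000086762, -2.07 ± 0.28). Next came sema4e (ENSDARG00000052997, -2.02 ± 0.17), BARX2 (ENSDARG00000041098, -2.02 ± 0.23), CDCA7 (ENSDARG00000077620, -2.02 ± 0.22), wnt11f2 (ENSDARG00000004256, -1.97 ± 0.18) and GPR37 (ENSDARG00000033296, -1.96 ± 0.20). The small nucleolar RNA loci SNORD54, snord79.2 (ENSDARG00000083254) and snord74 (ENSDARG00000083457) were listed at 0 in all 3 mock libraries. They were at 600, 425 and 764, 164, 232 and 127 and 116, 82.2 and 148 FPKM at 1 h. The MIR21 (ENSDARG00000082187) locus was at 169, 146 and 178 FPKM, against 9.69, 0 and 0 in mock. snord74 lost its call in 6 of 24 fits without 1 library (6.62 to 7.04). snord74 (6.80) and snord79.2 (7.43) lost their calls without the 4 GFP+ libraries numbered 1.

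Immediate early genes rose together at 1 h. In this list 34 of 42 rose, 0 fell and 8 did not pass (35 and 1 adjusted over the list alone, camera adjusted p = 1.3e-17, adjusted p = 0.299 with an estimated correlation). Its median was 1.07, and examples are the AP-1 genes fosl1b (ENSDARG00000079373, 2.95 ± 0.18) and FOSL2 (ENSDARG00000040623, 2.65 ± 0.24), MYC (ENSDARG00000007241, 0.93 ± 0.083) and DUSP4 (ENSDARG00000044688, 2.31 ± 0.21). Ribosome biogenesis genes rose likewise, and 39 of 48 rose, 0 fell and 9 did not pass (41 and 0 adjusted over the list alone, camera adjusted p = 7.2e-20, adjusted p = 0.581 with an estimated correlation). Examples were RRS1 (ENSDARG00000003941, 2.0 ± 0.14), nop2 (ENSDARG00000043304, 1.83 ± 0.14) and PPAN (ENSDARG00000022232, 1.79 ± 0.15). Of the heat shock and unfolded protein list 17 of 33 rose, 0 fell and 16 did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 2.73e-07, adjusted p = 0.299 with an estimated correlation). Examples were atf4b (ENSDARG00000038141, 1.22 ± 0.082), the mitochondrial chaperone HSPD1 (ENSDARG00000056160, 1.87 ± 0.16) and TRIB3 (ENSDARG00000016200, 1.98 ± 0.17). In the Jak/Stat3 list 12 of 23 rose, 1 fell and 10 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 0.000214, adjusted p = 0.486 with an estimated correlation). STAT3 (ENSDARG00000022712, 1.59 ± 0.23) rose, as did the cytokine il11b (ENSDARG00000058557, 3.54 ± 0.34) and the kinase JAK1 (ENSDARG00000020625, 1.43 ± 0.14). The feedback inhibitor SOCS3 (ENSDARG00000025428, 2.07 ± 0.48) rose with them. NF-kB and inflammation genes rose in part, and 14 of 32 rose, 3 fell and 15 did not pass (14 and 3 adjusted over the list alone, camera adjusted p = 0.00057, adjusted p = 0.724 with an estimated correlation). The receptor genes tnfrsf1a (ENSDARG00000018569, 2.03 ± 0.19) and TNFRSF21 (ENSDARG00000001807, 1.44 ± 0.19) were among them. Of the chemokine and migration list 10 of 29 rose, 2 fell and 17 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.00182, adjusted p = 0.724 with an estimated correlation). Examples were CXCL14 (ENSDARG00000056627, 1.18 ± 0.14) and the integrin ITGA5 (ENSDARG00000006353, 1.59 ± 0.20). Of the glycolysis and hypoxia list 15 of 29 rose, 2 fell and 12 did not pass (15 and 3 adjusted over the list alone, camera adjusted p = 0.00141, adjusted p = 0.486 with an estimated correlation). The regulator PFKFB3 (ENSDARG00000001953, 3.44 ± 0.25) rose and the growth factor VEGFA (ENSDARG00000034700, -0.97 ± 0.14) fell. Of the p53 and apoptosis list 14 of 37 rose, 6 fell and 17 did not pass (14 and 7 adjusted over the list alone, camera adjusted p = 0.0356, adjusted p = 0.703 with an estimated correlation). The proapoptotic BAX (ENSDARG00000020623, 1.11 ± 0.11) and the antiapoptotic BCL2L1 (ENSDARG00000008434, 0.85 ± 0.12) both rose.

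The S phase and mitosis, Fgf and Wnt/beta-catenin lists were lower in GFP+ cells at 1 h. In the S phase and mitosis list 1 of 54 rose, 38 fell and 15 did not pass (1 and 42 adjusted over the list alone, camera adjusted p = 1.45e-07, adjusted p = 0.724 with an estimated correlation). Its median was -0.60, with MCM5 (ENSDARG00000019507, -0.99 ± 0.15), NUSAP1 (ENSDARG00000002403, -1.21 ± 0.20), chaf1a (ENSDARG00000062152, -0.67 ± 0.12) and GINS2 (ENSDARG00000002304, -1.08 ± 0.20†) as examples. Of the Fgf list 1 of 25 rose, 11 fell and 13 did not pass (1 and 12 adjusted over the list alone, camera adjusted p = 0.00353, adjusted p = 0.724 with an estimated correlation). The ligand FGF8 (ENSDARG00000003399, -1.48 ± 0.18), the inhibitor SPRY2 (ENSDARG00000078308, -1.06 ± 0.14) and the receptor FGFR3 (ENSDARG00000004782, -0.92 ± 0.13) fell. ETV4 (-0.94 ± 0.18), FGFR1 (-1.05 ± 0.18), FGF10 (-0.54 ± 0.18†) and the replication clamp gene PCNA (ENSDARG00000054155, -0.44 ± 0.14†) fell too. Of the Wnt/beta-catenin list 3 of 43 rose, 18 fell and 22 did not pass (3 and 21 adjusted over the list alone, camera adjusted p = 0.00104, adjusted p = 0.724 with an estimated correlation). TCF7L1 (ENSDARG00000038159, -1.31 ± 0.12), wnt2 (-1.89 ± 0.24) and the antagonist dkk2 (ENSDARG00000076420, -1.29 ± 0.18) fell. The lateral line and supporting cell list was not called by camera (adjusted p = 0.174) and was called lower by fry (adjusted p = 0.0452), and 5 of 37 rose, 14 fell and 18 did not pass (adjusted over the list alone, 5 and 15). Its members SOX3 (ENSDARG00000053569, -1.74 ± 0.14), SOX2 (ENSDARG00000070913, -1.18 ± 0.16) and EYA4 (-1.20 ± 0.19) fell and KLF4 (ENSDARG00000079922, 1.53 ± 0.19) rose. The Notch list was not called either (camera adjusted p = 0.218), and 2 of 37 rose, 7 fell and 28 did not pass (adjusted over the list alone, 2 and 7). The inhibitor NUMB (ENSDARG00000027279, 1.86 ± 0.14) rose. The targets HEY2 (ENSDARG00000013441, -1.12 ± 0.17) and HEY1 (ENSDARG00000070538, -0.94 ± 0.18) and the receptor NOTCH3 (ENSDARG00000052139, -0.67 ± 0.13†) fell. Nor was the Bmp and Tgf-beta list called (camera adjusted p = 0.93), in which 7 of 40 rose, 7 fell and 26 did not pass (adjusted over the list alone, 7 and 8). Of the hair cell list 2 of 36 rose, 3 fell and 31 did not pass (adjusted over the list alone, 2 and 2). Its median was -0.022 while the camera direction was up, with an adjusted p of 0.732. In the set of genes reported whatever their result, her4.1 (ENSDARG00000056732, -0.59 ± 0.23), DLL1 (ENSDARG00000010791, -0.38 ± 0.18), ENSDARG00000020219 (-0.30 ± 0.15), which the names table also calls DLL1, and ATOH1 (ENSDARG00000055294, -0.24 ± 0.20) did not pass. Neither did POU4F3 (ENSDARG00000006206, 0.10 ± 0.27), LEF1 (ENSDARG00000031894, -0.13 ± 0.16), CDKN1B (ENSDARG00000029018, -0.19 ± 0.15) and CXCR4 (ENSDARG00000041959, -0.042 ± 0.20). FGF10 lost its call without mock replicates 2 (-0.48) or 3 (-0.44) or 1 h replicate 1 (-0.38). PCNA lost its call without mock replicates 1 (-0.33) or 2 (-0.37) or 1 h replicate 3 (-0.41), and with median-of-ratios scaling (-0.37) or without the 4 GFP+ libraries numbered 1 (-0.35).

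The limma test called 7211 genes in GFP+ cells at 1 h, 3046 higher and 4165 lower, against 7385 with median-of-ratios scaling, 3600 higher and 3785 lower, and 3815 in the own-groups model.

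**Figure D1:**
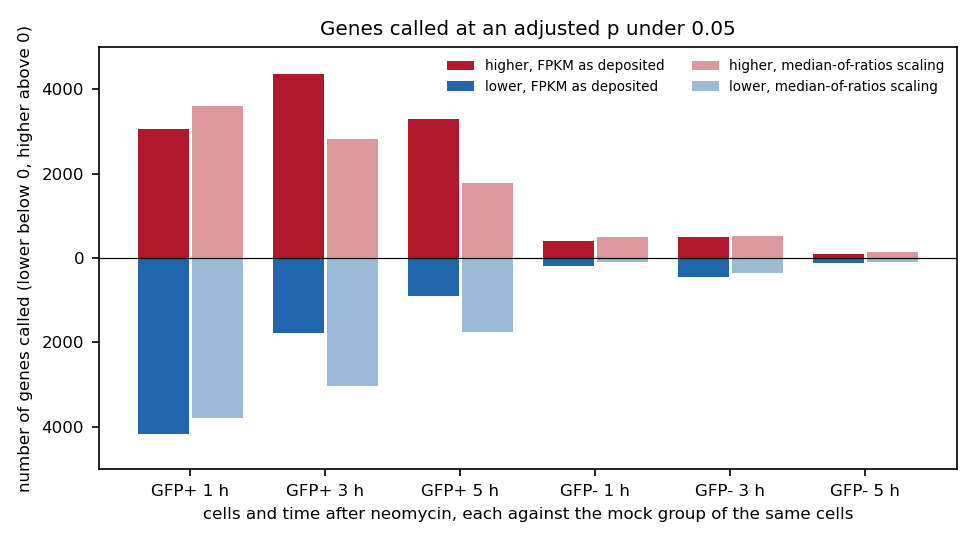
Number of genes called at an adjusted p under 0.05 against mock (y axis, higher above 0 and lower below 0) by cell population and time after neomycin (x axis), with FPKM as deposited (dark bars) and after median-of-ratios scaling (light bars). GFP+ cells show 7211, 6141 and 4202 called genes at 1, 3 and 5 h and GFP- cells 590, 965 and 228, and the share of higher calls in GFP+ cells at 3 and 5 h depends on the scaling.

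GFP+ cells 3 h after neomycin were compared with mock in the same way. The mmp13a level was 89.5 ± 87.4 FPKM against 2.75 ± 1.75 in mock (4.24 ± 0.66, adjusted p = 9.68e-05). The leptin gene lepb (ENSDARG00000045548, 4.11 ± 0.92), tinagl1 (ENSDARG00000061231, 3.11 ± 0.41), the relaxin gene rln3a (ENSDARG00000070780, 2.83 ± 0.39) and ODC1 (3.19 ± 0.42) rose too. They were followed by ABCF2 (ENSDARG00000038785, 2.45 ± 0.16) and HSP90AA1 (ENSDARG00000024746, 2.42 ± 0.23). The largest falls were in mfsd2al2 (ENSDARG00000075375, -2.47 ± 0.25), ms4a17a.9 (ENSDARG00000094854, -2.44 ± 0.81†), odam (ENSDARG00000074476, -2.40 ± 0.76†) and mgp (ENSDARG00000086189, -2.28 ± 0.26), which codes for matrix Gla protein. Lower were also negaly6 (-2.18 ± 0.21), MYOC (ENSDARG00000021789, -1.99 ± 0.48), rps11l (ENSDARG00000093606, -1.94 ± 0.31), SPON2 (ENSDARG00000002732, -1.90 ± 0.42†), the claudin cldn1 (ENSDARG00000040045, -1.89 ± 0.41) and mhc1uma (ENSDARG00000039164, -1.88 ± 0.36). The MIR21 locus stood at 13.1, 11.3 and 18.3 FPKM against 9.69, 0 and 0 in mock (2.76 ± 0.90†). ms4a17a.9 lost its call without mock replicates 1 (-2.26) or 3 (-2.29) or 3 h replicates 1 (-2.40) or 2 (-1.81), and without the 4 GFP+ libraries numbered 1 (-2.21). odam lost its call without mock replicates 2 (-2.29) or 3 (-2.07) or 3 h replicates 1 (-2.49) or 2 (-1.73). MIR21 lost its call without mock replicates 2 (2.19) or 3 (2.19) or 3 h replicates 1 (2.81) or 3 (2.58).

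Of the ribosome biogenesis list 45 of 48 rose, 2 fell and 1 did not pass (the same over the list alone, camera adjusted p = 2.1e-19, 0.581 with an estimated correlation) at 3 h. Its median was 1.05, with NOC2L (ENSDARG00000001754, 1.48 ± 0.13), BOP1 (ENSDARG00000063627, 1.54 ± 0.14) and the nucleolar methyltransferase FBL (ENSDARG00000053912, 1.64 ± 0.16) as examples. Heat shock and unfolded protein genes rose, and 17 of 33 rose, 0 fell and 16 did not pass (20 and 0 adjusted over the list alone, camera adjusted p = 5.51e-05, adjusted p = 0.486 with an estimated correlation). Examples were HSPD1 (2.63 ± 0.16), dnaja1 (ENSDARG00000030972, 1.45 ± 0.14) and HSPE1 (ENSDARG00000056167, 1.51 ± 0.16). In the S phase and mitosis list 20 of 54 rose, 1 fell and 33 did not pass (21 and 1 adjusted over the list alone, camera adjusted p = 0.00139, adjusted p = 0.828 with an estimated correlation). Its median was 0.40, and with median-of-ratios scaling it was 0.252 and 11 members rose. Examples were MCM4 (ENSDARG00000040041, 1.04 ± 0.13), RPA1 (ENSDARG00000003938, 0.80 ± 0.10), MCM3 (ENSDARG00000024204, 1.05 ± 0.15) and MCM5 (0.96 ± 0.15). PCNA rose as well (0.55 ± 0.14†). Notch genes went both ways, and 7 of 37 rose, 9 fell and 21 did not pass (7 and 10 adjusted over the list alone, camera adjusted p = 0.0312, adjusted p = 0.828 with an estimated correlation, 0.572 by fry). NUMB (0.87 ± 0.14) and the protease gene ADAM17 (ENSDARG00000093093, 0.78 ± 0.14) rose. The ligand gene dll4 (ENSDARG00000070425, -0.50 ± 0.10) and HEY2 (-0.83 ± 0.17†) fell. The Notch target her4.1 (-1.0 ± 0.23) fell as well, and DLL1 (0.60 ± 0.18†) rose. Of the Fgf list 1 of 25 rose, 5 fell and 19 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.754 with an estimated correlation, 0.261 by fry). ETV4 (-1.52 ± 0.18) and fgfbp2b (ENSDARG00000038056, -1.54 ± 0.33) fell. Of the glycolysis and hypoxia list 12 of 29 rose, 2 fell and 15 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 0.0429, adjusted p = 0.724 with an estimated correlation). Examples were ALDOA (ENSDARG00000011665, 0.55 ± 0.077) and GPI (ENSDARG00000012987, 0.82 ± 0.12). That list was not called with median-of-ratios scaling (adjusted p = 0.0815) or after subtraction of the GFP- share (adjusted p = 0.0778). DLL1 lost its call without mock replicate 1 (0.35) or 3 h replicate 2 (0.49), and with quantile normalization (0.40) or without the 4 GFP+ libraries numbered 1 (0.45). PCNA (0.37) and DLL1 (0.44) lost their calls with median-of-ratios scaling.

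Of the hair cell list 2 of 36 rose, 6 fell and 28 did not pass (2 and 6 adjusted over the list alone, camera adjusted p = 0.0103, 0.79 with an estimated correlation, 0.373 by fry) at 3 h. TEKT3 (ENSDARG00000045038, -1.37 ± 0.22) and pvalb8 (ENSDARG00000037790, -1.77 ± 0.29) fell. ATOH1 (0.76 ± 0.20), the gene of a transcription factor that starts hair cell differentiation, rose. Blood markers rose in GFP+ cells, 14 of 28 with 0 lower (the same over the list alone, camera adjusted p = 0.0031, 0.754 with an estimated correlation). Examples were SLC4A1 (2.47 ± 0.29), alas2 (ENSDARG00000038643, 1.39 ± 0.25) and gata1a (ENSDARG00000013477, 1.07 ± 0.20). The estimated GFP- share was higher too, so carry-over of blood cells stays open. The neuron list (median 0.49, camera adjusted p = 0.168) and the retina and lens list (median 0.56, camera adjusted p = 0.291) were not called. In the first 8 of 22 rose, 1 fell and 13 did not pass (adjusted over the list alone, 10 and 1), and in the other 4 of 23 rose, 0 fell and 19 did not pass (adjusted over the list alone, 4 and 0). Of the vessel, cartilage and fibroblast list 1 of 39 rose, 4 fell and 34 did not pass (the same over the list alone, camera adjusted p = 0.00179, 0.798 with an estimated correlation, 0.373 by fry). POSTN (ENSDARG00000043806, -1.19 ± 0.28) and ucmaa (ENSDARG00000027799, -1.72 ± 0.41†) fell. STAT3 (0.39 ± 0.23), SOCS3 (-0.23 ± 0.48), NOTCH3 (-0.065 ± 0.13), the second DLL1 gene (0.20 ± 0.15), FGFR1 (-0.45 ± 0.18) and FGF10 (-0.15 ± 0.18) did not pass. The same holds for SOX2 (-0.37 ± 0.16), CDKN1B (-0.38 ± 0.15), POU4F3 (-0.39 ± 0.27), LEF1 (0.14 ± 0.16) and CXCR4 (-0.14 ± 0.20). ucmaa lost its call without the 4 GFP+ libraries numbered 1 (-1.20).

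The limma test called 6141 genes at 3 h, 4358 higher and 1783 lower, a higher share of 71%. With median-of-ratios scaling 5849 were called, 2829 higher and 3020 lower (48.4%), and the median log2 change of all genes moved from 0.11 to 0. The own-groups model called 3793. The 3 h libraries differ from the mock ones in date and time of sampling, so neither can be told apart from the treatment here.

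**Figure D2:**
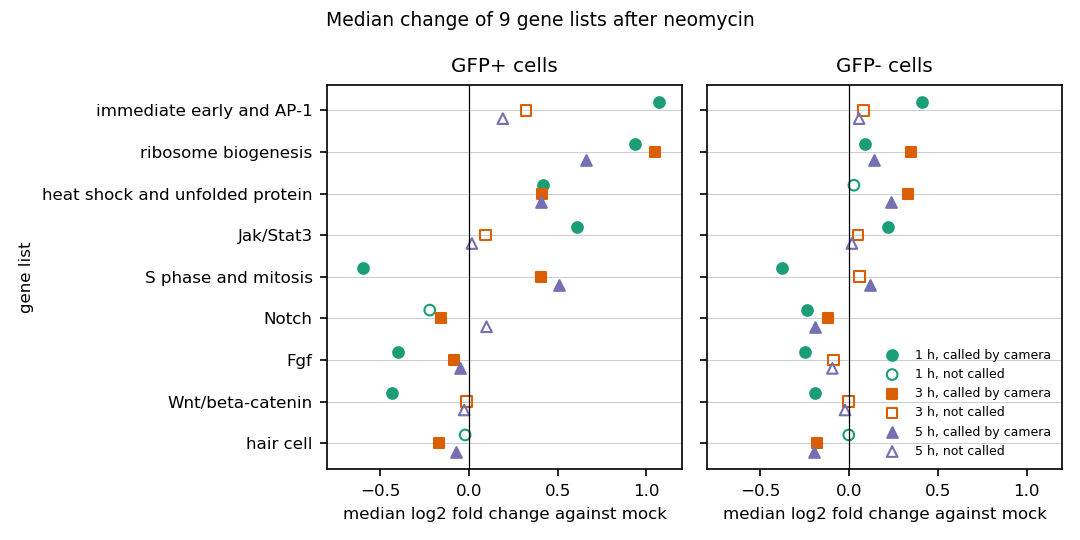
Median log2 fold change against mock (x axis) of 9 gene lists (y axis) in GFP+ cells (left) and GFP- cells (right) at 1, 3 and 5 h after neomycin. Filled marks are lists called by camera and open marks are not, and the S phase and mitosis median of GFP+ cells lies at -0.60 at 1 h, 0.40 at 3 h and 0.51 at 5 h.

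By 5 h after neomycin S phase genes were higher in GFP+ cells than in mock. Of the S phase and mitosis list 25 of 54 rose, 0 fell and 29 did not pass (29 and 0 adjusted over the list alone, camera adjusted p = 7.3e-08, 0.724 with an estimated correlation). Its median was 0.51, and examples are RPA1 (0.92 ± 0.10), POLA1 (0.71 ± 0.097), chaf1a (0.77 ± 0.12) and CHAF1B (ENSDARG00000056473, 0.82 ± 0.13†). PCNA stood at 164 ± 17.9 FPKM against 101 ± 22.0 in mock (0.72 ± 0.14†, adjusted p = 0.0013). Ribosome biogenesis genes were still up, and 34 of 48 rose, 2 fell and 12 did not pass (41 and 2 adjusted over the list alone, camera adjusted p = 1.42e-12, 0.719 with an estimated correlation). Examples were BOP1 (1.14 ± 0.14), FBL (1.21 ± 0.16) and BMS1 (ENSDARG00000054154, 1.12 ± 0.15). Of the heat shock and unfolded protein list 14 of 33 rose, 0 fell and 19 did not pass (17 and 0 adjusted over the list alone, camera adjusted p = 0.000495, 0.581 with an estimated correlation). Examples were HSPD1 (1.88 ± 0.16), HSPA4 (ENSDARG00000018989, 0.93 ± 0.095) and ASNS (ENSDARG00000016375, 0.83 ± 0.12). In the Notch list 6 of 37 rose, 1 fell and 30 did not pass (adjusted over the list alone, 6 and 1). The ligand genes dlb (ENSDARG00000004232, 1.11 ± 0.21†) and DLL1 (0.91 ± 0.18†) and the receptor gene NOTCH1 (ENSDARG00000052094, 0.66 ± 0.14†) rose, while dll4 fell (-0.45 ± 0.10†). The list was not called, and its median was 0.098 while the camera direction was down, with an adjusted p of 0.998. The second DLL1 gene, ENSDARG00000020219, rose by 1.25 ± 0.15. Of the hair cell list 1 of 36 rose, 5 fell and 30 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 0.0032, 0.748 with an estimated correlation, 0.454 by fry). TEKT3 (-1.07 ± 0.22†) and pvalb8 (-1.38 ± 0.29) fell. ATOH1 (0.80 ± 0.20) rose. GFP- cells had the hair cell list lower too at 3 and 5 h (medians -0.181 and -0.196, camera adjusted p = 0.0313 and 0.0174, 0.334 and 0.231 by fry). GFP+ medians were -0.169 and -0.0763, and the differences were not called (camera adjusted p = 0.214 and 0.183). TEKT3 lost its call with a pseudocount of 0.1 (-1.24). NOTCH1 (0.41) and pvalb8 (-0.95) lost their calls without the 4 GFP+ libraries numbered 1.

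The largest rises at 5 h outside small-RNA loci were in SLC4A1 (2.26 ± 0.29), the cyclin gene ccndx (ENSDARG00000019741, 1.94 ± 0.22), jac1 (ENSDARG00000092521, 1.88 ± 0.57) and HSPD1. They were followed by the peptide hormone gene apela (ENSDARG00000094729, 1.8 ± 0.19), the peptidase gene THOP1 (ENSDARG00000013776, 1.76 ± 0.13), the mitochondrial import gene TOMM40 (ENSDARG00000092112, 1.73 ± 0.25) and hbae1.1 (1.73 ± 0.41†). ABCF2 (1.71 ± 0.16) and jac11 (ENSDARG00000076388, 1.62 ± 0.25) came next. Carry-over of blood cells stays open for SLC4A1, hbae1.1 and the blood list below, as at 3 h. The largest falls were in ms4a17a.9 (-2.67 ± 0.81†), odam (-2.51 ± 0.76†), mgp (-1.90 ± 0.26), s100a11 (ENSDARG00000093628, -1.75 ± 0.50) and DPYD (ENSDARG00000086853, -1.73 ± 0.29). Next came the ferritin gene fthl30 (ENSDARG00000077360, -1.73 ± 0.31), bglap (ENSDARG00000058414, -1.70 ± 0.49†), mfsd2al2 (-1.69 ± 0.25), tac3a (ENSDARG00000093089, -1.54 ± 0.31†) and kcnip3a (ENSDARG00000034229, -1.51 ± 0.23). SNORD54 and MIR181B1 were listed at 0 in all 3 mock libraries and at 313, 183 and 670 and 71, 41.6 and 75.9 FPKM at 5 h. jac1 lost its call without mock replicates 2 (1.77) or 3 (1.64) or 5 h replicates 1 (1.70) or 2 (1.93). ms4a17a.9 lost its call without mock replicates 1 (-2.48) or 3 (-2.51) or 5 h replicates 1 (-2.63) or 2 (-1.92). odam lost its call without mock replicates 2 (-2.39) or 3 (-2.18) or 5 h replicate 2 (-1.26). s100a11 lost its call without mock replicate 1 (-1.61) or 5 h replicates 1 (-1.67) or 2 (-1.61). bglap lost its call without mock replicates 1 (-1.67) or 3 (-1.22) or 5 h replicate 1 (-1.50), and with a pseudocount of 0.1 (-2.34). ms4a17a.9 (-2.45), s100a11 (-1.53) and bglap (-1.47) lost their calls without the 4 GFP+ libraries numbered 1.

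Of the blood list 6 of 28 rose, 0 fell and 22 did not pass (adjusted over the list alone, 6 and 0), and the list was not called (camera adjusted p = 0.0686). It was called higher with a block by replicate number (adjusted p = 0.0328, 8 members higher and 0 lower) and with median-of-ratios scaling (adjusted p = 0.005, 3 higher and 1 lower). The heme synthesis gene alas2 rose (1.19 ± 0.25†). Skeletal muscle genes were lower as a list, and 0 of 16 rose, 3 fell and 13 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.000916, 0.581 with an estimated correlation, 0.0706 by fry). The called members were TNNC2 (ENSDARG00000070835, -0.97 ± 0.22†), TNNT3 (ENSDARG00000068457, -0.84 ± 0.24†) and ckmb (ENSDARG00000040565, -0.74 ± 0.23). STAT3 (0.47 ± 0.23), SOCS3 (-0.10 ± 0.48), NOTCH3 (0.24 ± 0.13), her4.1 (-0.27 ± 0.23), ETV4 (-0.096 ± 0.18) and FGFR1 (0.029 ± 0.18) did not pass at 5 h. FGF10 (0.19 ± 0.18), SOX2 (0.28 ± 0.16), CDKN1B (-0.41 ± 0.15), POU4F3 (-0.22 ± 0.27), LEF1 (0.13 ± 0.16) and CXCR4 (-0.078 ± 0.20) did not pass either. TNNT3 lost its call without mock replicate 3 (-0.75) or 5 h replicate 3 (-0.70). ckmb lost its call without mock replicates 1 (-0.64) or 2 (-0.79) or 5 h replicates 1 (-0.79) or 2 (-0.62). TNNC2 (-0.66), TNNT3 (-0.92) and ckmb (-0.69) lost their calls without the 4 GFP+ libraries numbered 1. In all, 4202 genes were called at 5 h, 3306 higher and 896 lower (78.7% higher), against 3529 with 50.1% higher under median-of-ratios scaling and 1745 in the own-groups model. The date and the time of sampling differ from the mock libraries here too.

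**Figure D3:**
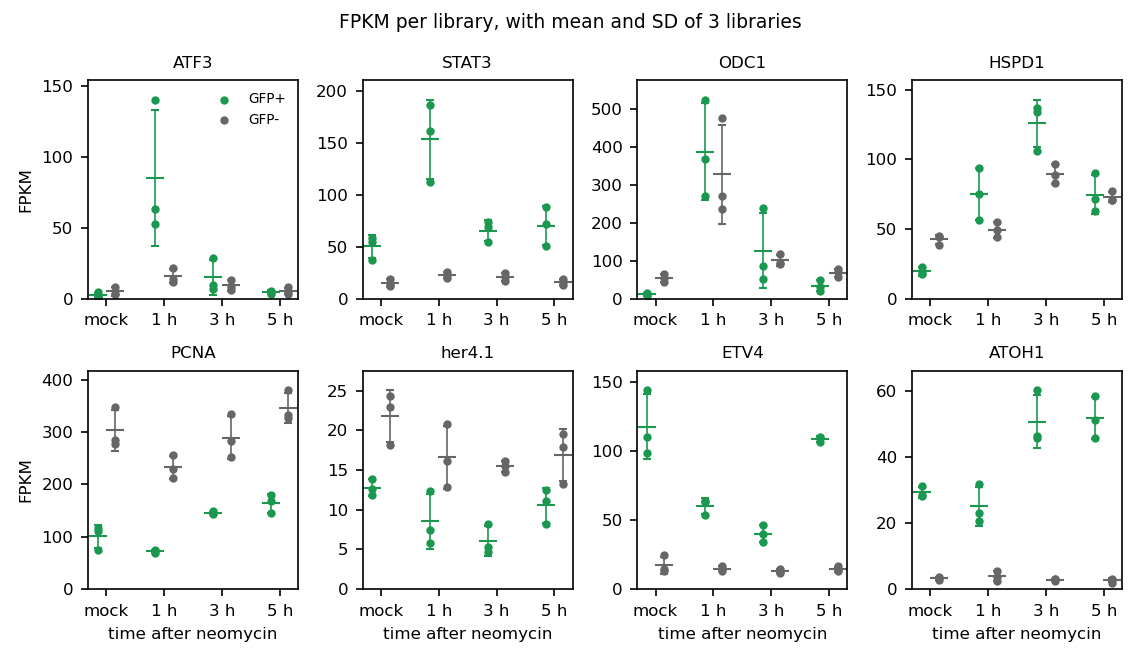
FPKM (y axes, each starting at 0) of 8 genes in every library of GFP+ cells (green) and GFP- cells (grey) by group (x axes, mock and 1, 3 and 5 h after neomycin), with horizontal marks for the means and bars for the SD of 3 libraries. In GFP+ cells ATF3 stands at 85.1 ± 47.9 FPKM at 1 h, and ETV4 is lowest at 3 h, at 40.2 ± 6.10 FPKM.

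The same contrasts in GFP- cells show the changes after neomycin in the rest of the sorted cells. At 1 h PER2 (3.67 ± 0.69), the gelatinase gene MMP9 (ENSDARG00000042816, 3.08 ± 0.51†) and the transporter gene SLC16A6 (ENSDARG00000060246, 2.54 ± 0.30) rose most. tnfsf12 (ENSDARG00000069376, -1.07 ± 0.17†), anxa5a (ENSDARG00000026406, -1.26 ± 0.24†) and nkl.2 (ENSDARG00000058673, -0.99 ± 0.26†) fell most. Of the immediate early list 4 of 42 rose, 0 fell and 38 did not pass (14 and 0 adjusted over the list alone, camera adjusted p = 2.39e-12, adjusted p = 0.486 with an estimated correlation). Examples were GADD45A (ENSDARG00000043581, 1.3 ± 0.21†) and FOSL2 (1.43 ± 0.24). Of the glycolysis and hypoxia list 3 of 29 rose, 0 fell and 26 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 1.44e-08, adjusted p = 0.189 with an estimated correlation). PFKFB4 (ENSDARG00000029075, 1.46 ± 0.19) was an example. S phase and mitosis genes were lower as a list, and 0 of 54 rose, 3 fell and 51 did not pass (0 and 17 adjusted over the list alone, camera adjusted p = 3.36e-13, adjusted p = 0.581 with an estimated correlation). The list median was -0.38, and MCM5 stood at -0.72 ± 0.15†. Fgf genes were lower as a list, and 0 of 25 rose, 4 fell and 21 did not pass (0 and 4 adjusted over the list alone, camera adjusted p = 0.000135, adjusted p = 0.677 with an estimated correlation). Of the Wnt/beta-catenin list 0 of 43 rose, 4 fell and 39 did not pass (0 and 4 adjusted over the list alone, camera adjusted p = 0.000653, adjusted p = 0.724 with an estimated correlation, 0.0946 by fry). anxa5a lost its call without 1 h replicate 1 (-1.08). nkl.2 lost its call in 18 of 24 fits without 1 library (-1.14 to -0.69). It also did with median-of-ratios scaling (-0.92), a pseudocount of 0.1 (-1.20), no filter (-0.99) or a filter at 5 FPKM (-0.99). MCM5 lost its call without mock replicate 3 (-0.59) or 1 h replicate 3 (-0.65). In all 590 genes were called, 411 higher and 179 lower (69.7% higher, or 83.9% with median-of-ratios scaling). The count was 216, 372 and 326 without 1 h replicates 1, 2 and 3, 327 and 332 without mock replicates 2 and 3, and 96 in the own-groups model, and 924 with quantile normalization.

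At 3 h in GFP- cells the chaperone gene hsc70 (ENSDARG00000012381, 3.31 ± 0.30) stood at 19.6 ± 2.12 FPKM against 1.1 ± 0.374 in mock. The globin gene hbae5 (ENSDARG00000045142, 2.08 ± 0.43†) and the ghrelin gene ghrl (ENSDARG00000054239, 2.74 ± 0.75†) rose. The ribosomal protein gene rps11l (-1.83 ± 0.31) and the peptide transporter gene SLC15A1 (ENSDARG00000044528, -1.89 ± 0.42†) fell. The chemokine gene cxcl11.5 (ENSDARG00000092423) was listed at 0 in all 3 libraries, against 10.1, 5.35 and 2.01 FPKM in mock. MIR21 was at 0 likewise, against 7.54, 14.3 and 9.53. The locus mir126a (ENSDARG00000081476) was at 26.9, 23.2 and 57.5 FPKM against 0, 0 and 0.00112. Of the heat shock and unfolded protein list 5 of 33 rose, 0 fell and 28 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 3.11e-08, 0.299 with an estimated correlation). Examples were HSPD1 (1.05 ± 0.16) and XBP1 (ENSDARG00000035622, 0.47 ± 0.072†). Blood markers rose in part, and 8 of 28 rose, 0 fell and 20 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.00169, adjusted p = 0.748 with an estimated correlation, 0.125 by fry). Examples were klf1 (ENSDARG00000017400, 0.99 ± 0.14†) and gata1a (1.29 ± 0.20†). ghrl lost its call in 17 of 24 fits without 1 library (2.30 to 2.99), and without a filter on low values (2.74) or with a random block by sort (2.74). SLC15A1 lost its call without mock replicates 1 (-1.8) or 3 (-1.69) or 3 h replicate 3 (-1.65). cxcl11.5 lost its call without mock replicate 1 (-2.13). MIR21 (-3.66 to -3.25) and mir126a (4.70 to 5.33) each lost the call in 6 of 24 fits without 1 library, and MIR21 with median-of-ratios scaling (-3.31). hbae5 (2.1) and ghrl (3.01) lost their calls with a pseudocount of 0.1. cxcl11.5 lost its call in the own-groups model. The 965 calls (505 higher, 460 lower) fell to 582, 360 and 604 without mock replicates 1, 2 and 3 and to 491, 512 and 268 without 3 h replicates 1, 2 and 3. They were 589 with a pseudocount of 0.1 and 63 in the own-groups model.

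At 5 h in GFP- cells hsc70 (3.09 ± 0.30†) and the heme synthesis gene CPOX (ENSDARG00000062025, 1.69 ± 0.20†) were among the largest rises. The gene anxa5a (-1.88 ± 0.24†) and the chemokine gene ccl38a.4 (ENSDARG00000041917, -2.31 ± 0.36†) fell. Listed at 0 in all 3 libraries at 5 h was cxcl11.5. Of the blood list 5 of 28 rose, 0 fell and 23 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.000273, adjusted p = 0.724 with an estimated correlation, 0.234 by fry). Examples were SLC4A1 (1.62 ± 0.29†) and UROD (ENSDARG00000006818, 1.24 ± 0.22†). ccl38a.4 lost its call with a pseudocount of 0.1 (-2.72). SLC4A1 (1.39) and UROD (1.06) lost their calls without 5 h replicate 2. cxcl11.5 lost its call in 5 of 24 fits without 1 library (-2.58 to -2.13) and in the own-groups model. There were 228 calls, 105 higher and 123 lower (46.1% higher, or 61.9% with median-of-ratios scaling). They fell to 73 and 140 without mock replicates 2 and 3 and to 67 and 137 without 5 h replicates 2 and 3. They were 420 with quantile normalization, 133 with a pseudocount of 0.1 and 18 in the own-groups model.

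Whether GFP+ and GFP- cells changed differently was tested as a difference of changes. It cancels a date effect that is equal in both populations as log2(FPKM + 1). At 1 h the difference was positive for LIN28A (3.62 ± 0.43) and il11b (3.42 ± 0.48) and negative for MAP3K15 (ENSDARG00000013310, -2.18 ± 0.21). Of the ribosome biogenesis list 33 of 48 had a positive difference, 0 a negative one and 15 did not pass (37 and 0 adjusted over the list alone, camera adjusted p = 2.1e-19, adjusted p = 0.581 with an estimated correlation). Examples were RRS1 (1.85 ± 0.19) and nop2 (1.37 ± 0.20). In the immediate early list 15 of 42 had a positive difference, 0 a negative one and 27 did not pass (21 and 2 adjusted over the list alone, camera adjusted p = 1.87e-09, adjusted p = 0.574 with an estimated correlation). Examples were fosl1b (3.16 ± 0.26) and JUNB (ENSDARG00000074378, 2.71 ± 0.45). Of the heat shock and unfolded protein list 13 of 33 had a positive difference, 0 a negative one and 20 did not pass (14 and 0 adjusted over the list alone, camera adjusted p = 5.01e-08, adjusted p = 0.299 with an estimated correlation). Examples were atf4b (1.09 ± 0.12) and dnaja1 (1.62 ± 0.20). Of the Jak/Stat3 list 3 of 23 had a positive difference, 0 a negative one and 20 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.724 with an estimated correlation, 0.0733 by fry), and STAT3 was at 0.98 ± 0.33 (adjusted p = 0.0529). The lists that were lower in GFP+ cells at 1 h were not called in this difference, with a camera adjusted p of 0.183 for S phase and mitosis, 0.305 for Fgf and 0.135 for Wnt/beta-catenin. In all 3085 genes differed in their change, 1673 with a positive and 1412 with a negative difference, and 1992 in the own-groups model.

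At 3 h the difference was positive for rln3a (2.96 ± 0.55) and tinagl1 (2.55 ± 0.57) and negative for hsc70 (-4.47 ± 0.42) and mfsd2al2 (-2.27 ± 0.36). Of the ribosome biogenesis list 18 of 48 had a positive difference, 0 a negative one and 30 did not pass (40 and 0 adjusted over the list alone, camera adjusted p = 6.57e-13, adjusted p = 0.703 with an estimated correlation). Examples were GAR1 (ENSDARG00000076526, 1.12 ± 0.19) and EBNA1BP2 (ENSDARG00000054980, 0.87 ± 0.16). With median-of-ratios scaling 7 members passed. In the S phase and mitosis list 2 of 54 had a positive difference, 0 a negative one and 52 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.00311, adjusted p = 0.838 with an estimated correlation, 0.139 by fry). These were RPA1 (0.75 ± 0.15) and MCM4 (0.76 ± 0.18†), and the list median was 0.32. mfsd2al2 lost its call with a pseudocount of 0.1 (-2.07). MCM4 lost its call without GFP- mock replicate 3 (0.65), GFP- 3 h replicate 3 (0.70) or GFP+ mock replicate 1 (0.66), and with median-of-ratios scaling (0.59), with quantile normalization (0.52) or without the 4 GFP+ libraries numbered 1 (0.62). The 1362 called genes, 1182 positive and 180 negative (86.8% positive), became 755 with 54.7% positive under median-of-ratios scaling and 700 under quantile normalization. The median log2 difference of all genes moved from 0.13 to -0.016 with median-of-ratios scaling. Leaving out GFP- mock replicate 3 gave 826 genes, GFP+ 3 h replicate 1 gave 886, and GFP- 3 h replicates 1 and 3 gave 821 and 756.

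At 5 h the difference was positive for ccndx (1.85 ± 0.31) and apela (1.8 ± 0.28) and negative for hsc70 (-4.10 ± 0.42). Of the S phase and mitosis list 2 of 54 had a positive difference, 0 a negative one and 52 did not pass (11 and 0 adjusted over the list alone, camera adjusted p = 0.000174, adjusted p = 0.817 with an estimated correlation, 0.0823 by fry). These were RPA1 (0.68 ± 0.15†) and POLA1 (0.60 ± 0.14†), and the list median was 0.40. Of the Notch list 4 of 37 had a positive difference, 0 a negative one and 33 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.0425, adjusted p = 0.828 with an estimated correlation, 0.0684 by fry). They were dlb (1.22 ± 0.29†), DLL1 (1.06 ± 0.25†), ADAM17 (0.81 ± 0.20†) and NOTCH1 (0.76 ± 0.20†). With median-of-ratios scaling 0 members passed (camera adjusted p = 0.109). ccndx lost its call with a pseudocount of 0.1 (1.81). RPA1 lost its call without GFP- mock replicate 3 (0.59) or GFP- 5 h replicate 2 (0.62). POLA1 (0.51 to 0.59) and dlb (0.95 to 1.27) lost their calls in 6 and 9 of 24 fits without 1 library. DLL1 (0.80 to 1.07) and ADAM17 (0.66 to 0.86) lost theirs in 7 and 16 of the 24. NOTCH1 lost its call in 17 of 24 fits without 1 library (0.61 to 0.80), and with scaling outside the 10 most abundant loci (0.85) or without a filter on low values (0.76). RPA1 (0.47), POLA1 (0.42), dlb (1.02), DLL1 (0.86), ADAM17 (0.61) and NOTCH1 (0.56) lost their calls with median-of-ratios scaling. With quantile normalization these calls ended too (0.48, 0.40, 1.02, 0.85, 0.66 and 0.58). RPA1 (0.70), POLA1 (0.63), ADAM17 (0.75) and NOTCH1 (0.51) lost their calls without the 4 GFP+ libraries numbered 1. The 617 called genes, 566 positive and 51 negative (91.7% positive), became 126 with 57.1% positive under median-of-ratios scaling, 174 under quantile normalization and 180 in the own-groups model. The median log2 difference of all genes moved from 0.16 to -0.005 with median-of-ratios scaling. Leaving out GFP- mock replicate 3 gave 231 genes, GFP+ 5 h replicates 2 and 3 gave 353 and 387, and GFP- 5 h replicates 1, 2 and 3 gave 371, 254 and 408.

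The 5 h and 3 h GFP+ cells share a date. RAP1GAP (ENSDARG00000056554, 1.6 ± 0.14†, adjusted p = 6.76e-06), which codes for a GTPase-activating protein, and ETV4 (1.42 ± 0.18†, adjusted p = 0.000708) were higher at 5 h than at 3 h. ETV4 stood at 109 ± 1.95 against 40.2 ± 6.10 FPKM. The kinase subunit gene prkag3a (ENSDARG00000017537, 1.4 ± 0.30†) rose, and tinagl1 (-1.99 ± 0.41†) and ODC1 (-1.68 ± 0.42†) fell. MIR181B1 was listed at 0 in all 3 libraries at 3 h and at 71, 41.6 and 75.9 FPKM at 5 h. Of the ribosome biogenesis list 0 of 48 rose, 3 fell and 45 did not pass (0 and 22 adjusted over the list alone, camera adjusted p = 7.93e-16, adjusted p = 0.677 with an estimated correlation, 0.0564 by fry). Its median was -0.35, and nop2 (-0.71 ± 0.14†) was an example. In the Notch list 3 of 37 rose, 0 fell and 34 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 9.22e-05, 0.703 with an estimated correlation, 0.0931 by fry). The lateral line and supporting cell list had the same counts (3 and 0 adjusted over the list alone, camera adjusted p = 0.000647, 0.703 with an estimated correlation, 0.125 by fry). prkag3a lost its call without 3 h replicates 1 (1.39) or 3 (1.33) or 5 h replicates 1 (1.36) or 2 (1.29), and with a pseudocount of 0.1 (1.83). tinagl1 lost its call without 3 h replicate 1 (-1.52) or 5 h replicates 1 (-1.70) or 2 (-1.82). ODC1 lost its call in 18 of 24 fits without 1 library (-1.8 to -1.08), and with quantile normalization (-1.66) or without a filter on low values (-1.68). nop2 lost its call without 3 h replicate 1 (-0.60) or 5 h replicate 1 (-0.62). MIR181B1 lost its call without 3 h replicates 1 (5.95) or 3 (5.95). prkag3a (1.34), tinagl1 (-1.23), ODC1 (-0.79), nop2 (-0.51) and MIR181B1 (5.84) lost their calls without the 4 GFP+ libraries numbered 1. In all 390 genes were called, 234 higher and 156 lower. The count fell to 90 and 135 without 3 h replicates 1 and 3, to 249 and 200 without 5 h replicates 1 and 2, and to 1 in the own-groups model. It was 140 without the 4 GFP+ libraries numbered 1 and 254 with scaling outside the 10 most abundant loci.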

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

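The tests chosen only after the result was seen were the subtraction of the GFP- share for S phase genes, median-of-ratios scaling and the FPKM sums for the share of higher calls, and the date tests for S phase genes and for GFP+ cells alone. Settings chosen after seeing the data are named above.

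Changes after neomycin that differed between GFP+ and GFP- cells, by the test of the difference itself, are listed here. They number 3085 genes at 1 h, 1362 at 3 h and 617 at 5 h. At 1 h the median difference of changes (log2) was 0.183 for the Jak/Stat3 list, 0.70 for immediate early genes, 0.429 for heat shock and unfolded protein, 0.246 for NF-kB and inflammation, 0.342 for chemokine and migration and 0.811 for ribosome biogenesis. At 3 h it was -0.0277 for Fgf, -0.053 for Wnt/beta-catenin, 0.323 for S phase and mitosis, 0.704 for ribosome biogenesis and -0.175 for vessel, cartilage and fibroblast markers. At 5 h it was 0.289 for Notch, 0.398 for S phase and mitosis, -0.116 for chemokine and migration, 0.503 for ribosome biogenesis, -0.225 for skeletal muscle, -0.15 for retina and lens and -0.215 for vessel, cartilage and fibroblast markers. The calls of all these lists ended with an estimated correlation (smallest adjusted p over all tests 0.189). With fry the calls held for immediate early, heat shock and ribosome biogenesis genes at 1 h and ribosome biogenesis at 3 h, and those of the others ended.

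Single genes differed as well. At 1 h the log2 difference of changes was 5.45 for MIR21, 3.62 for LIN28A and 3.42 for il11b, and -2.73 for VWA2, -2.48 for tspan2b and -2.18 for MAP3K15. The VWA2 and tspan2b calls ended in 19 (-2.99 to -2.40) and 5 (-2.35 to -2.17) of 24 fits without 1 library. SNORD54 (adjusted p = 0.00822) and MIRLET7G (adjusted p = 0.0469) were listed at 0 in all libraries of a group, and the MIRLET7G call ended in 17 of 24 fits without 1 library (5.19 to 7.49). At 3 h the difference was 2.96 for rln3a, 2.55 for tinagl1, 2.31 for ODC1, -4.475 for hsc70, -2.27 for mfsd2al2 and -1.99 for olfml2ba, and MIR21 (adjusted p = 0.00732) was listed at 0 in the 3 h GFP- libraries. The ODC1 (1.71 to 2.30) and olfml2ba (-2.0 to -1.68) calls each ended in 7 of 24 fits without 1 library. At 5 h it was 1.85 for ccndx, 1.8 for apela, -4.10 for hsc70, -1.64 for mfsd2al2 and -1.63 for mgp. The mgp call ended in 7 of 24 fits without 1 library (-1.61 to -1.54), and that of mfsd2al2 without GFP- mock replicate 3 (-1.52). SNORD36C (adjusted p = 0.0319), MIR181B1 (adjusted p = 0.0497) and ccl38a.4 (adjusted p = 0.0225) were listed at 0 in a group, and their calls ended in 10 of 24 fits without 1 library (10.40 to 12.41), in 21 of 24 fits without 1 library (5.84 to 6.78) and without GFP- 5 h replicate 1 (2.02).

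The S phase and mitosis genes called higher in GFP+ cells at 3 h (20 members) and 5 h (25 members) are the first pattern. Carry-over of GFP- cells, in which these genes are high (median 28.7 FPKM in mock GFP- and 8.51 in mock GFP+ cells), is argued against as the whole cause: 19 and 24 of the members were still called after the share had been subtracted. Scaling is argued against at 5 h, where 20 of the 25 were still called with median-of-ratios scaling, and stays open at 3 h, where 11 of the 20 were. A date effect that both populations share cannot be told apart from the change. The median difference of changes was 0.323 at 3 h and 0.398 at 5 h while fry did not pass (adjusted p = 0.139 and 0.0823). Camera called the list higher in GFP- cells at 5 h too (median 0.116). A response to neomycin remains an open, untested explanation, as does a date effect on GFP+ cells.

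The second pattern is the excess of higher calls in GFP+ cells at 3 and 5 h (71% and 78.7%). Carry-over of GFP- cells at the estimated share is argued against, since 69.4% and 78.4% of the calls were higher after subtraction. An effect of the 10 most abundant loci cannot be told apart: they held 39.5% to 44.4% of the FPKM sum in mock, 36.1% to 39% at 3 h and 35.8% to 38.3% at 5 h, the direction that it needs. After scaling to the other loci 84.7% and 88.2% of the calls were higher, but that setting also evens out the FPKM sums. The mean log2 sum was higher in mock by 0.297 than at 3 h and by 0.253 than at 5 h, more than the median changes of 0.109 and 0.0992. The scaling of the deposited FPKM is a candidate explanation: with median-of-ratios scaling the shares were 48.4% and 50.1%. That scaling assumes that most genes do not change, so a real general rise, as a biological alternative, was not tested.

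The third pattern is the date. Of the genes called at 3 h and 5 h in GFP+ cells, 1243 (20.2%) and 579 (13.8%) were also called in the same direction in the difference from GFP- cells, and 20 simulated sets of changes shared by both populations gave at most 13 and 5. A shared date effect therefore does not account for these genes as a set. In the fit with median-of-ratios scaling 706 and 118 genes were called in both, and 543 and 106 of them were among the 1243 and 579. For the other called genes any shared date effect stays open. A date effect on GFP+ cells alone cannot be told apart from neomycin, because 0 mock GFP+ libraries carry the later date.

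The 6 libraries of a comparison of 2 groups make 10 splits, too few for a share under 0.05. In each such comparison 1 split, the real one, gave as many genes. The real count and the highest of the other splits were 7211 and 84 in GFP+ cells at 1 h, 6141 and 2 at 3 h, 4202 and 30 at 5 h, 590 and 9 in GFP- cells at 1 h, 965 and 6 at 3 h, 228 and 3 at 5 h, 15235 and 1 for GFP+ against GFP- cells, and 390 and 4 for 5 h against 3 h. For the differences of changes 100 splits within both populations were used, and 11, 8 and 9 of them, the real one included, gave as many genes as the real 3085, 1362 and 617, with highest other counts of 4919, 6401 and 2336, so this count does not exclude chance. It follows a structure of the samples: 10 of 10, 7 of 7 and 8 of 9 splits that kept the GFP+ labels and mixed the GFP- ones were as large. Of the splits that mixed the GFP+ labels, 0 were as large at 1, 3 and 5 h, with highest counts of 452, 8 and 7.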

How the results depend on the processing

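Settings chosen after seeing the data are listed with the methods. Counts within 1.5 times the values reported, under a setting not named here, are not repeated. The cause of the shifts below was not tested, except that fewer libraries, or a stricter threshold, call fewer genes by construction. With a pseudocount of 0.1 the GFP- counts at 3 and 5 h were 589 and 133. Median-of-ratios scaling gave 755 and 126 genes for the differences of changes at 3 and 5 h, and quantile normalization gave 700 and 174, and 924 and 420 in GFP- cells at 1 and 5 h. With only the groups of the contrast the counts were 3815, 3793 and 1745 in GFP+ cells at 1, 3 and 5 h, 96, 63 and 18 in GFP- cells, 1992 and 180 for the differences at 1 and 5 h, and 1 for 5 h against 3 h. With a threshold of 1 on the log2 change they were 1626, 1040 and 447, then 156, 177 and 72, then 972, 316 and 118 for the differences, 7852 for GFP+ against GFP- cells, and 40 for 5 h against 3 h. A random block by sort (correlation 0.117) gave 970 for the difference at 5 h. For 5 h against 3 h, leaving out the 4 GFP+ libraries numbered 1 gave 140 and scaling outside the 10 most abundant loci gave 254.

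Leaving out each library in turn gave 216 to 764 genes in GFP- cells at 1 h, 268 to 1089 at 3 h and 67 to 235 at 5 h. It gave 756 to 1640 and 231 to 773 for the differences at 3 and 5 h, and 90 to 521 for 5 h against 3 h. The lowest counts came without 1 h replicate 1 (216), 3 h replicate 3 (268) and 5 h replicate 2 (67) of GFP- cells, 3 h replicate 3 (756) and mock replicate 3 (231) of GFP- cells, and 3 h replicate 1 of GFP+ cells (90). Counts in GFP+ cells kept within 1.5 times (6253 to 7240, 4854 to 6502 and 2955 to 4509). Of the 103 list calls, 0 held with an estimated correlation and 46 with fry (57 ended, and with 9 others fry called 55). With median-of-ratios scaling 96 kept call and direction, and after share subtraction 97 did. Of the 6 that ended there, 3 were blood or retina lists, whose members set the share. The others were glycolysis and hypoxia in GFP+ cells at 3 h (adjusted p = 0.0778), and in the differences NF-kB and inflammation at 1 h (adjusted p = 0.0511) and Wnt/beta-catenin at 3 h (adjusted p = 0.0523). With a block by replicate number the counts were 7468, 6424 and 4424 in GFP+ cells, 721, 1157 and 276 in GFP- cells, 3324, 1531 and 715 for the differences, 15352 for GFP+ against GFP- cells and 482 for 5 h against 3 h, and all 103 list calls were kept. That block added 3 list calls: skeletal muscle (lower, adjusted p = 0.0429) at 3 h and blood (higher, adjusted p = 0.0328) at 5 h in GFP+ cells, and p53 and apoptosis (higher, adjusted p = 0.0429) in GFP- cells at 1 h. Median-of-ratios scaling added 3 as well: lateral line and supporting cell at 3 h (lower, adjusted p = 0.0324) and blood at 5 h (higher, adjusted p = 0.005) in GFP+ cells, and Fgf in the difference at 5 h (negative, adjusted p = 0.0118). The deviations from group means of libraries of 1 number correlated across genes at -0.0866 to 0.17 (median 0.0354), with 7 of 84 pairs over 0.1. As a hint from the data and not from the design, 23 of 24 libraries correlated best with their own number.

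Over all named genes and settings, 13689 of 14518 values kept their direction and side of the threshold, 711 were weaker, 86 stronger and 32 reversed, and 0 of the reversed ones had been called. A model of the contrast's own groups alone ended the calls of 94 of 396 values of named genes at an equal log2 change (daggers in the report). The reversed values, as log2 changes in GFP+ cells, were with median-of-ratios scaling CXCR4 at 1 h 0.0227, LEF1 at 3 h -0.0223 and at 5 h -0.0344, and FGFR1 at 5 h -0.146. With quantile normalization they were LEF1 at 3 h -0.0348 and at 5 h -0.0394, and FGFR1 at 5 h -0.122. Without the 4 GFP+ libraries numbered 1 they were POU4F3 -0.0654 and CXCR4 0.0112 at 1 h, LEF1 -0.0398 at 3 h and FGFR1 -0.029 at 5 h. With scaling outside the 10 most abundant loci they were FGF10 0.0142, CXCR4 0.00765 and NOTCH3 0.102 at 3 h, and ETV4 0.0248, SOCS3 0.0141 and CXCR4 0.0307 at 5 h. With 1 library left out the ranges were -0.13 to 0.095 for CXCR4 and -0.0684 to 0.26 for POU4F3 at 1 h, -0.53 to 0.116 for SOCS3 and -0.16 to 0.000452 for NOTCH3 at 3 h, and at 5 h -0.19 to 0.0597 for CXCR4, -0.39 to 0.00593 for POU4F3, -0.63 to 0.273 for SOCS3, -0.0601 to 0.11 for FGFR1, -0.00189 to 0.24 for LEF1 and -0.21 to 0.0577 for ETV4. Depth is known only as relative depth (0.729 to 1.26), so no floor in reads is given for genes near 1 FPKM.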

Other observations

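The list tests were fixed in advance, but these lists are a selection of the 275 tests. At 1 h in GFP+ cells, 4 of 22 rose, 6 fell and 12 did not pass (adjusted over the list alone, 5 and 6) in the list of G1 cyclins and cell cycle inhibitors. Its median was -0.12 while the camera direction was up (adjusted p = 0.93). In the retinoic acid and steroid list 4 of 25 rose, 4 fell and 17 did not pass (adjusted over the list alone, 7 and 4). Its median was -0.054 while the camera direction was up (adjusted p = 0.747). Gut, liver, pancreas and kidney markers were called higher as a list, and 2 of 44 rose, 0 fell and 42 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.0313, 0.828 with an estimated correlation, 0.226 by fry). With median-of-ratios scaling that list was not called (adjusted p = 0.0512).

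In GFP- cells the retina and lens list was called higher at all 3 times with few single genes passing. The medians were 0.50 at 1 h, 0.47 at 3 h and 0.61 at 5 h, and 1, 2 and 1 of 23 members passed (1, 3 and 3 adjusted over the list alone). The adjusted p was 0.000157, 0.0247 and 2.01e-05 with camera, 0.724, 0.828 and 0.703 with an estimated correlation and 0.175, 0.341 and 0.164 with fry. Notch genes were called lower as a list in GFP- cells at 1, 3 and 5 h with 0 members passing at any time (0, 0 and 4 lower adjusted over the list alone; 1, 2 and 1 lower with a block by replicate number). The medians were -0.23, -0.12 and -0.19. The adjusted p was 0.000273, 0.0113 and 0.00169 with camera, 0.724, 0.798 and 0.724 with an estimated correlation and 0.0705, 0.261 and 0.125 with fry. Fry called neither list at any time. In these cells camera and fry both called glycolysis and hypoxia higher at 3 and 5 h (fry adjusted p = 0.00149 and 0.0227). They called heat shock genes higher at 5 h (0.00765) and pigment and glia markers lower at 3 and 5 h (0.011 and 0.0365).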
